A study of Homo sapiens with 6 samples.

How the data were processed

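RNA from 6 clonal strains of human bone marrow stromal cells was measured on U133 Plus 2.0 expression arrays of Affymetrix, with 1 array per strain. Bone marrow stromal cells are the adherent, fibroblast-like cells of marrow, and such a strain is a culture grown from a single colony. Per the labels' protocols, marrow cells were plated thinly in medium with 20% serum, dexamethasone and an ascorbate salt. Colonies were picked after 14 days and expanded over several passages, and the cells then went to RNA isolation and to transplantation in vivo. The labels put 3 strains in a multipotent group and 3 in a unipotent group. Which tissues the strains formed, and whether they came from 1 donor or several, is not given in the sources used here. The p-values therefore set the group difference against the spread between strains of a group, and do not speak for other donors. The strains carry clone numbers that pair nothing across the groups, and the replicate numbers used here are names only.

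The authors made the values with RMA, per the submitters' processing notes, which give no version. RMA is a method that corrects the background, quantile-normalizes the arrays and summarises the probes of a probe set on a log scale. The deposited values were treated as log2 because RMA gives log2, and the base itself is not given in the sources used here. Over the 6 arrays all 54675 probe sets had a median within 0.001 of 0. The deposited log2 values are therefore relative to each probe set's own median, a step that the sources used here do not describe. Differences between strains are kept by this centring. The absolute signal is lost, so it is unknown which probe sets lay near the background, and no level of a gene can be set against another gene's. The medians of the 6 arrays lay between -0.0028 and 0.0040. The number of arrays limits the precision, and the median standard error of a difference over genes was 0.117.

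Gene names came from the array's annotation table, which can be old. It paired 41097 probe sets with 1 gene symbol and 1801 with several, and 11777 were not listed. Of the probe sets with 1 symbol, 41043 had a gene identifier that matched the RefSeq table of assembly GRCh38.p14, and 0 symbols needed an update. Probe sets with several symbols or none, the 62 Affymetrix control probe sets and those of genes that reveal a donor's sex stayed out of the gene tests. No genome build belongs to the values, so no coordinates are given. The RefSeq table served only for names and for which genes neighbour each other.

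The design fixed before the data were examined took the probe set with the highest mean for each gene, left out the lowest 40 percent of genes by mean and fitted a trend of variance on level. Centred values allow none of these steps. In their place each gene was represented by the probe set with the largest standard deviation over all 6 arrays, chosen blind to group, with no filter and no trend. This left 19721 genes, of which 10499 had more than 1 probe set. A gene's difference is therefore that of its most variable probe set, and other probe sets of the same gene can give smaller ones. Of the 43 genes past the threshold that had other probe sets, 22 had none with at least 50% of the difference. Where a difference is printed and no other probe set of that gene reached 50% of it, the value or the median of the others is given.

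Differences were estimated as multipotent minus unipotent with limma 3.58.1 (lmFit and eBayes) in R 4.3.3 and tested on both sides, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. All adjusted p-values of genes come from this fit. The fit had 4 residual degrees of freedom, to which the shared variance estimate added 2.15. Fixed before the data were examined were 25 gene lists. They were tested with camera of limma at a preset inter-gene correlation of 0.01, with adjustment over the lists, and again with an estimated correlation and with fry, which asks whether a list's genes move, on balance, one way. Members of a list were also counted with p-values adjusted over the list alone. Similarity was the Pearson correlation across genes, and genes are not independent replicates. With 3 strains against 3, an exact permutation test cannot give a p below 0.1.

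The genes to name were set by a rule fixed before the data were examined. It took the 12 largest differences in each direction among genes past the threshold whose groups did not overlap. In each list it took up to 4 members past the threshold, or the members of smallest p until 2 were named, and it added the most different marker of each other cell type. Members named because they passed only when adjusted over the list alone, the other genes past the threshold and the 6 largest differences short of it among genes not yet named were chosen after their values were seen.

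The alternatives tried were robust eBayes, array weights, every probe set on its own, the mean of a gene's probe sets, a repeated quantile normalization, centring of each array, other thresholds, other list tests, Spearman correlation and leaving out each strain in turn. Chosen after the data were seen were a filter on genes of low spread, the removal of probe sets whose names end in _s_at or _x_at, which can match several transcripts, and the mean of the cell cycle list as a covariate. The fit was tested on simulated data with 200 changed genes among 19721 in 10 runs for this comparison. It called 11.2% of the changes of 0.5 log2 units, 72.0% of those of 1, 94.0% of those of 2 and 99.2% of those of 4. False calls were 6.5 per run on average. Simulated genes varied independently, with the same SD in all strains and no choice among probe sets. Real arrays differ in this, so these rates need not hold for them.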

Results

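The data were gene expression profiles of 6 clonal strains of human bone marrow stromal cells, each grown from a single colony. The study asked how 3 strains classed as multipotent differed in expression from 3 strains classed as unipotent, that is, from strains of narrower differentiation potential. Each strain gave 1 array, and 19721 genes were compared. Values are log2 signals relative to the median of the 6 arrays, so they give differences between strains and no absolute level.

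Multipotent strains had higher expression of 17 genes and lower expression of 40. The largest increase was in OGN, which encodes osteoglycin, a small leucine-rich proteoglycan of bone and other connective tissues. It was 35.3-fold higher, at 2.74 ± 0.44 in multipotent and -2.40 ± 0.12 in unipotent strains (SD, n = 3 each; difference 5.14, SE 0.22, adjusted p = 0.0020). The largest decrease was in SYNPO2, which encodes the actin-binding protein synaptopodin 2 of muscle cells. It was 115-fold lower, at -3.31 ± 0.51 against 3.54 ± 0.65 (SD, n = 3 each; difference -6.85, SE 0.39, adjusted p = 0.0063). The 6 other SYNPO2 probe sets differed by -6.01 to -0.21, with a median of -3.21. The smallest fold among the 57 genes was 1.53 and the median was 5.82.

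**Figure D1:**
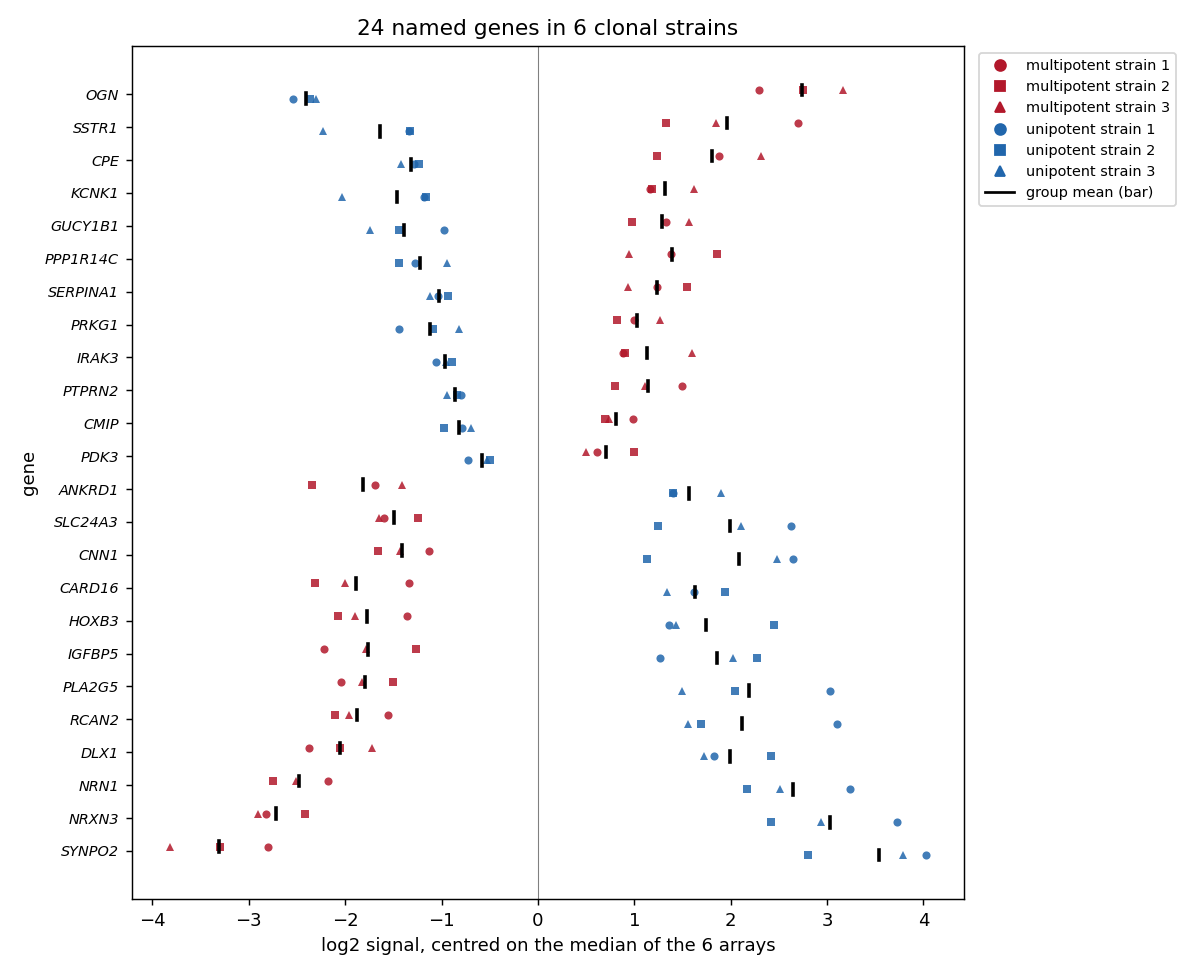
Log2 signal relative to the median of the 6 arrays (horizontal axis) for the 12 genes with the largest positive and the 12 with the largest negative difference past the threshold (vertical axis). Points are strains, red for multipotent and blue for unipotent, and black bars are group means. OGN lies at 2.74 against -2.40 and SYNPO2 at -3.31 against 3.54. In all 24 genes the groups do not overlap, which was a condition for naming them.

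Among genes past the threshold, the largest increase after OGN was in SSTR1, a somatostatin receptor, at 12.1-fold higher (difference 3.60, SE 0.41, adjusted p = 0.038). SSTR1 lost its call in each fit that left out 1 strain. CPE, the carboxypeptidase that trims prohormones, was 8.72-fold higher (difference 3.12, SE 0.27, adjusted p = 0.018). GUCY1B1, a subunit of the nitric oxide receptor guanylate cyclase, was 6.41-fold higher, and PRKG1, a protein kinase activated by the cyclic GMP that this enzyme makes, was 4.42-fold higher (adjusted p = 0.019 for both). The potassium channel gene KCNK1 was 6.87-fold higher and the phosphatase inhibitor gene PPP1R14C 6.13-fold higher. SERPINA1, which encodes alpha-1-antitrypsin, was 4.82-fold higher, and IRAK3, an inhibitor of Toll-like receptor signalling, 4.27-fold higher. PTPRN2, CMIP and PDK3, a kinase that inhibits pyruvate dehydrogenase, completed the 12 largest increases past the threshold, with differences of 2.00, 1.63 and 1.29. PDK3 also lost its call in each fit that left out 1 strain.

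Among genes past the threshold, the largest decreases after SYNPO2 were in NRXN3 and NRN1. NRXN3, a neurexin, was 53.4-fold lower (difference -5.74, SE 0.34) and NRN1, which encodes neuritin, 34.8-fold lower (difference -5.12, SE 0.29), both with an adjusted p of 0.0063. The homeobox gene DLX1 was 16.5-fold lower (adjusted p = 0.0063) and HOXB3 11.5-fold lower (adjusted p = 0.024). RCAN2, a regulator of calcineurin, was 15.9-fold lower and SLC24A3, a sodium, potassium and calcium exchanger, 11.2-fold lower. The secreted phospholipase gene PLA2G5 was 15.8-fold lower, IGFBP5, which encodes a binding protein of insulin-like growth factors, 12.2-fold lower, and CARD16, an inhibitor of caspase-1, 11.5-fold lower. CNN1, which encodes the smooth muscle protein calponin 1, was 11.3-fold lower, and ANKRD1, an ankyrin repeat gene of muscle, 10.5-fold lower.

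In each of the 57 genes, all 3 multipotent strains lay on one side of all 3 unipotent strains. With 3 strains against 3, p-values this small leave little room for overlap. The 24 largest were also named only if their groups did not overlap. The separation is therefore no added support. Over all 19721 genes the groups did not overlap in 18.3%, against 10% by chance. In limma 2412 genes had an unadjusted p under 0.05, where 986 are expected with no difference. Both expectations are averages, and genes that vary together can exceed them by chance in a single split. These 2 values were not compared with the other splits. The counts, and which genes passed, depended on single strains. The counts fell to 8 higher and 19 lower without unipotent replicate 3 and to 9 and 12 without multipotent replicate 3. Without multipotent replicate 2 they were 13 and 20. Without unipotent replicate 1 they were 12 and 40, with 7 and 27 of the main calls among them. Without unipotent replicate 2 they were 14 and 50 (9 and 24 of the main calls). Without multipotent replicate 1 they were 23 and 41 (8 and 20 of the main calls). With genes of low spread left out they were 43 and 86. They were 10 and 14 with the cell cycle mean as a covariate, which takes up a residual degree of freedom and so lowers power by itself. The size of a difference also depended on the probe set. Of the 19 among the 24 largest past the threshold that had other probe sets, 12 had another with at least 50% of the log2 difference. Among those 12, the median of the others could still be far smaller, as in SYNPO2 (-3.21), KCNK1 (0.10), SERPINA1 (0.39) and PLA2G5 (-1.19). In SSTR1, PRKG1, IRAK3, DLX1, IGFBP5, HOXB3 and CARD16 no other reached 50%. The medians of their others were 0.10, 0.47, 0.47, -0.30, -0.63, -0.23 and -0.04.

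Smooth muscle and pericyte contractile genes were the list with the largest shift. Of its 22 measured members, 21 had a negative difference, 3 passed over all genes and 15 passed adjusted over the list alone, all lower in multipotent strains. Besides SYNPO2 and CNN1, NOTCH3 passed, a receptor of vascular smooth muscle cells and pericytes, at 5.43-fold lower (difference -2.44, SE 0.29, adjusted p = 0.044), although its other probe set gave -0.11. Of the 6 fits that left out 1 strain, SYNPO2 passed in 6, but CNN1 and NOTCH3 in 1 each. Among the members that passed adjusted over the list alone, and were chosen after their values were seen, were the actin cytoskeleton genes ACTA2 (difference -1.91, SE 0.40), TAGLN (-1.49, SE 0.24) and MYL9 (-1.25, SE 0.20, and -0.51 in its other probe set), and ACTG2 (-2.65, SE 0.79), whose other probe set gave 0.02. The mean of the list was -0.57 ± 0.13 in multipotent and 0.83 ± 0.36 in unipotent strains (SD, n = 3 each; exact permutation p = 0.1, the smallest this design allows). Camera gave an adjusted p of 1.3e-14 at the preset correlation, and adjusted p = 0.33 with an estimated correlation.

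Osteoblast genes were higher on average in multipotent strains, with 16 of 24 measured members positive. OGN was the 1 of 24 measured members that passed over all genes. Adjusted over the list alone, 5 were higher and 1 was lower. The higher ones besides OGN were OMD, which encodes osteomodulin (difference 3.31, SE 0.66), PDPN, which encodes podoplanin (2.94, SE 0.49), the bone morphogenetic protein gene BMP2 (1.40, SE 0.25) and COL1A2, a chain of type I collagen (0.74, SE 0.11). The lower one was IBSP, which encodes bone sialoprotein (-2.12, SE 0.49). In COL1A2 and IBSP the other probe sets gave medians of 0.07 and -0.37. OMD, PDPN and IBSP were chosen after their values were seen. The mean difference of the list was 0.49 and its median 0.11, so the mean rested mostly on OGN, OMD and PDPN. Camera gave an adjusted p of 0.014, which was 0.051 without unipotent replicate 1 and 0.16 on ranks, and adjusted p = 0.33 with an estimated correlation. Fry gave an adjusted p of 0.022.

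Genes of the factors by which marrow stroma supports blood formation were lower on average in multipotent strains, with 15 of 18 measured members negative and a mean difference of -0.76. The mean of this niche factor list was -0.34 ± 0.19 in multipotent and 0.42 ± 0.20 in unipotent strains (SD, n = 3 each; exact permutation p = 0.1, the smallest this design allows). With 1 probe set per gene, none of the 18 passed, either over all genes or adjusted over the list alone. The Notch ligand gene JAG1 differed by -2.08 (SE 0.57, adjusted p = 0.24). When every probe set was tested, another of its 6 was lower past the threshold (-1.96, SE 0.21, adjusted p = 0.038), and the remaining 4 ran from -1.76 to 0.0043. EBF3, a transcription factor gene, differed by -2.17 (SE 0.61, adjusted p = 0.25). Camera gave an adjusted p of 0.0091, and adjusted p = 0.33 with an estimated correlation.

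Of 21 measured surface markers of stromal stem and progenitor cells, 1 passed over all genes, MCAM, which encodes CD146 of perivascular stromal cells, 3.84-fold lower in multipotent strains (difference -1.94, SE 0.21, adjusted p = 0.035). The only other probe set paired with MCAM alone gave 0.17. Probe sets paired with several symbols were left out of this comparison, so any that match MCAM were not counted. MCAM passed in 1 of the 6 fits that left out 1 strain. Adjusted over the list alone, 2 were higher (PDPN and CD44) and 6 lower (CD200, BST2, MCAM, NGFR, ITGA11 and NT5E). CD200 differed by -4.49 (SE 0.64, adjusted p = 0.067, and -2.06 in its other probe set) and NGFR by -1.36 (SE 0.17, adjusted p = 0.053). CD44, CD200, ITGA11 and NT5E were chosen after their values were seen. The list as a whole was not shifted in camera (mean difference -0.37, adjusted p = 0.073), but passed without unipotent replicate 2 (0.039) and without multipotent replicate 2 (0.023). With an estimated correlation the camera adjusted p over all strains was 0.63.

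**Figure D2:**
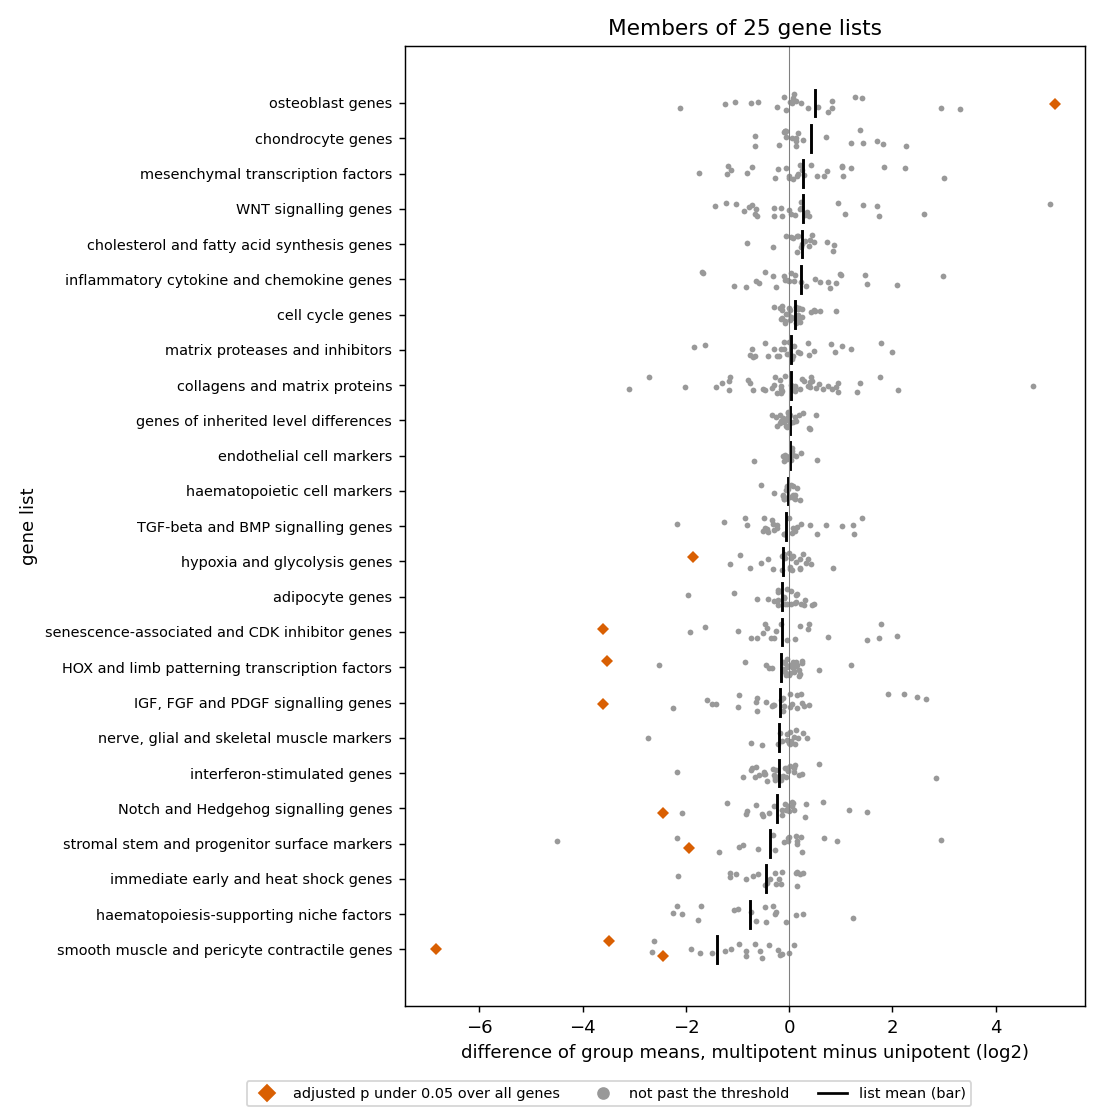
Difference of the group means, multipotent minus unipotent, in log2 units (horizontal axis) for the measured members of each of the 25 gene lists (vertical axis). Orange diamonds passed over all genes, grey points did not, and black bars are list means, which run from -1.40 for the contractile genes to 0.49 for the osteoblast genes.

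Of the 25 lists, 3 more passed in camera with no member past the threshold over all genes. In all 3 the strain means of the list overlapped between the groups. The exact permutation p of the list mean was 0.3 for the cholesterol, 0.2 for the immediate early and 0.4 for the interferon list. Cholesterol and fatty acid synthesis genes were shifted upward, with 15 of 18 positive and a mean difference of 0.24 (adjusted p = 0.010, and adjusted p = 0.63 with an estimated correlation). HMGCS1, an early enzyme of cholesterol synthesis, differed by 0.87 (SE 0.23), while STARD4, a sterol carrier and the 1 member that passed adjusted over the list alone, differed by -0.81 (SE 0.17). This shift did not pass without unipotent replicate 2 (adjusted p = 0.059) or without multipotent replicate 3 (0.087), and its mean was 0.36 without multipotent replicate 1. Immediate early and heat shock genes were shifted downward, with 15 of 20 negative and a mean difference of -0.45 (adjusted p = 0.017, and adjusted p = 0.52 with an estimated correlation). ATF3 differed by -2.16 (SE 0.50; median of its other probe sets -0.37) and EGR3 by -1.15 (SE 0.34), and 0 members passed adjusted over the list alone. That shift did not pass without multipotent replicate 1 (adjusted p = 0.086) or without probe sets ending in _s_at and _x_at (0.29). Interferon-stimulated genes were also shifted downward, with 25 of 33 negative and a mean difference of -0.19 (adjusted p = 0.017, and adjusted p = 0.64 with an estimated correlation). Without unipotent replicate 1 the mean difference was -0.055 (adjusted p = 0.54), and over the other omissions of 1 strain it lay between -0.27 and -0.12. BST2, an antiviral membrane protein, differed by -2.17 (SE 0.37) and was the 1 member lower adjusted over the list alone, and IFI27 differed by 2.85 (SE 0.70).

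Growth factor and patterning lists held single genes that passed without a shift of the list in camera. Among 31 genes of IGF, FGF and PDGF signalling, IGFBP5 was lower, and adjusted over the list alone 2 were higher (FGF18 and PDGFRL) and 4 lower (IGFBP5, DUSP6, FGFR2 and IGFBP7). IGFBP7 differed by -0.99 (SE 0.18; median of its other probe sets -0.34), and the other FGFR2 probe sets had a median of -0.068. That list had a mean difference of -0.17 and an adjusted p of 0.065 in camera and 0.030 in fry, and adjusted p = 0.34 with an estimated correlation. It passed in camera without unipotent replicate 2 (0.045) and without multipotent replicate 2 (0.038), and its mean was -0.11 without multipotent replicate 1. Among 30 HOX and limb patterning genes, HOXB3 was lower, and its neighbour HOXB4 differed by -0.46 (SE 0.08) and was lower adjusted over the list alone (camera adjusted p = 0.51). Most genes of the HOXA cluster were not analysed here. In the Notch and Hedgehog list, NOTCH3 was the 1 of 25 genes that passed by both adjustments, and SMO differed by 0.33 (SE 0.09; camera adjusted p = 0.21). Among 26 hypoxia and glycolysis genes, HK2, which encodes hexokinase 2, was 3.64-fold lower (difference -1.86, SE 0.13, adjusted p = 0.013) and the only one lower adjusted over the list alone, while P4HA1 differed by 0.43 (SE 0.11, and 0.11 in its other probe set; camera adjusted p = 0.78). Among 23 senescence-associated genes and CDK inhibitors IGFBP5 was lower, and IGFBP7 joined it adjusted over the list alone. That list's adjusted p in camera was 0.17, and 0.042 without multipotent replicate 2, against 0.64 over all strains with an estimated correlation.

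In the lists of matrix proteins, of mesenchymal transcription factors and of TGF-beta and BMP signalling, no member passed over all genes. Of 51 collagens and matrix proteins, 5 were higher and 2 lower adjusted over the list alone (camera adjusted p = 0.58). The 5 were FBLN2 (difference 2.11, SE 0.29), COL3A1 (1.75, SE 0.23), DCN, ELN and COL1A2, and the 2 were THBS1 (-2.01, SE 0.36) and FN1 (-1.16, SE 0.23). The 4 other COL3A1 probe sets gave 0.11 to 1.21 (median 0.20), of which that at 1.21 passed when every probe set was tested (SE 0.14, adjusted p = 0.048). No other FN1 probe set reached 50% of the difference (median -0.10). Of 28 mesenchymal transcription factors, 4 were higher (MKX, PRRX2, TWIST1 and PRRX1) and 1 lower (ZEB2) adjusted over the list alone. TWIST1 differed by 1.02 (SE 0.21) and PRRX2 by 1.05 (SE 0.22). Camera gave that list an adjusted p of 0.31, and 0.045 without unipotent replicate 2, against 0.64 over all strains with an estimated correlation. Of 29 genes of TGF-beta and BMP signalling, BMP2 was higher and INHBA (-2.17, SE 0.38) and LTBP1 (-0.43, SE 0.09) were lower adjusted over the list alone (camera adjusted p = 0.32). Of the genes named for IGF, FGF and PDGF signalling and in this paragraph, DCN, ELN, THBS1, FN1, MKX, PRRX1, ZEB2, LTBP1, FGF18, PDGFRL, DUSP6 and FGFR2 were chosen after their values were seen.

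In 5 further lists 0 members passed in limma over all genes or over the list alone. Of 27 adipocyte genes, 11 had a positive difference, and ANGPTL4 differed by -0.62 (SE 0.12) and FASN by 0.48 (SE 0.13, and 0.026 in its other probe set; camera adjusted p = 0.40). Of 22 chondrocyte genes, 13 were positive, and COL9A2 differed by 0.27 (SE 0.10) and MATN2 by 1.42 (SE 0.57, and 0.0099 in its other probe set). The camera adjusted p of the chondrocyte list was 0.20, and 0.032 without multipotent replicate 1, against 0.63 over all strains with an estimated correlation. Of 29 genes of WNT signalling, AXIN2 differed by 1.42 (SE 0.28; median of its other probe sets 0.064) and CCN4 by 1.70 (SE 0.38; camera adjusted p = 0.92). Of 29 inflammatory genes, TNFSF10 differed by -1.69 (SE 0.45) and PTGS2 by -1.68 (SE 0.49; camera adjusted p = 0.86). Of 31 matrix proteases and inhibitors, PLAT differed by -1.84 (SE 0.37) and TIMP1 by -0.30 (SE 0.08; camera adjusted p = 0.51).

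Cell cycle genes varied more between the strains of a group than between the groups. Their mean was 0.12 ± 0.73 in multipotent and 0.01 ± 0.32 in unipotent strains (SD, n = 3 each; exact permutation p = 0.8), and 0 of 30 members passed by either adjustment. CCNA2 differed by 0.90 (SE 0.41), or by 0.43 without multipotent replicate 3. E2F1 differed by -0.13 (SE 0.09), or by -0.082 without unipotent replicate 1, with 0.057 in its other probe set. The camera adjusted p at the preset correlation was 0.51. It was 0.00028 at a mean difference of 0.44 without multipotent replicate 2 and 0.010 at -0.27 without multipotent replicate 3. The estimated correlation of this list was 0.84, far above the preset 0.01, and with it the camera adjusted p over all strains was 0.98.

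Markers of other cell types that a marrow culture could hold did not pass in limma over all genes. Of 20 haematopoietic markers the largest difference was in ITGB2 (-0.54, SE 0.83), which ran from -1.35 to -0.021 without single strains. MS4A1 differed by 0.20 (SE 0.12), or 0.10 without unipotent replicate 1, and CD14 by -0.29 (SE 0.18, and -0.48 to -0.16 without single strains; camera adjusted p = 0.97). Of 16 endothelial markers the largest was in TEK (-0.68, SE 1.17, and 0.045 in its other probe set), which ran from -1.51 to 0.60 without single strains, while ECSCR differed by 0.54 (SE 0.24) and MMRN1 by -0.11 (SE 0.07; camera adjusted p = 0.86). Of 18 nerve, glial and skeletal muscle markers, the calcium-binding protein gene S100B was lower adjusted over the list alone (-2.74, SE 0.34, adjusted p = 0.051 over all genes), although its other probe set gave -0.04, and CKM differed by -0.52 (SE 0.15; camera adjusted p = 0.51). Of 24 genes whose level commonly differs between people by inheritance, CAT was higher adjusted over the list alone (0.41, SE 0.08), and CHI3L2 differed by 0.53 (SE 0.16; camera adjusted p = 0.97).

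The mean, the median and the direction in camera differed in sign in 5 lists. The mean and median were -0.17 and 0.01 for HOX and limb patterning genes, -0.12 and 0.02 for hypoxia and glycolysis genes, and -0.19 and 0.005 for nerve, glial and skeletal muscle markers, each with a downward direction in camera. Without single strains the HOX mean lay between -0.27 and -0.066. The mean and median were 0.04 and -0.01 for matrix proteases and 0.01 and -0.03 for genes of inherited level differences, again with a downward direction. Without single strains the protease mean lay between -0.075 and 0.11 and that of inherited level differences between -0.010 and 0.037. Over all 25 lists, 6 passed in camera at the preset correlation and 0 with an estimated one. Fry passed 3, the osteoblast, contractile, and IGF, FGF and PDGF lists.

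Expression profiles were more alike within the groups than between them. The mean correlation across genes was 0.19 between arrays of the same group and -0.31 between arrays of different groups, a difference of 0.50 (one-sided exact permutation p = 0.1, the smallest this design allows). Centring each probe set on the 6 arrays pulls such correlations below 0. The first principal component held 43.1% of the variance and separated the groups. Multipotent replicate 1 correlated with the other multipotent strains at 0.05 and 0.09, whereas these correlated at 0.38 with each other. The median SD within the group was 0.142 among multipotent and 0.123 among unipotent strains, a log2 ratio of 0.21. The log2 ratio was 0.047 after a repeated quantile normalization.

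**Figure D3:**
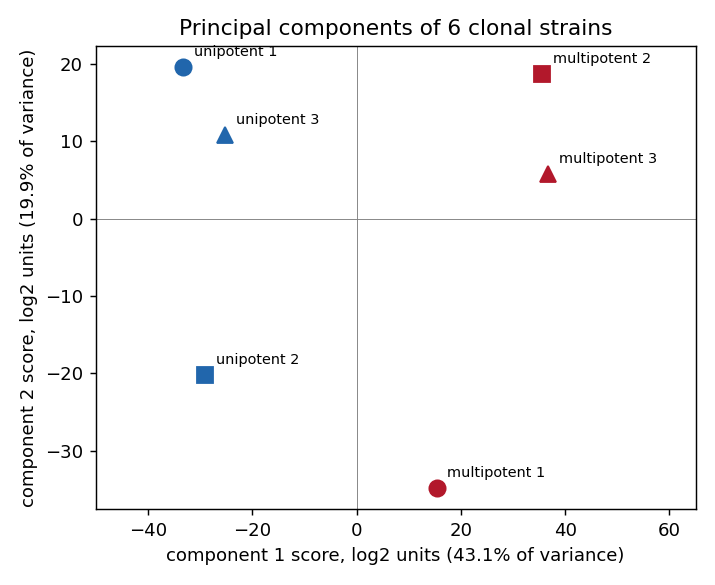
Scores of the 6 strains on the first principal component (horizontal axis, 43.1% of the variance) and the second (vertical axis, 19.9%), in log2 units. Multipotent strains (red) lie at 15.4 to 36.8 on the first component and unipotent strains (blue) at -33.3 to -25.2.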

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

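Probe sets without a single gene name were outside the main comparison, and 13486 of them were tested in the same way. A difference between the groups past the threshold was found in 5 that were higher and 10 that were lower in multipotent strains, and 1128 had an unadjusted p under 0.05. The largest differences among these 15 were 2.83 (SE 0.20, adjusted p = 0.017) in a probe set that has no gene name here and -2.80 (SE 0.08, adjusted p = 6.7e-05) in a probe set that the annotation pairs with several genes. Both were chosen after their values were seen.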

How the results depend on the processing

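The filter on low spread, the removal of probe sets ending in _s_at and _x_at and the cell cycle covariate were chosen after the data were seen. Filters and a variance trend based on level were not run, because the values are centred; the setting with no filter and no trend became the main one, and the alternative for linear values did not apply. What signal over background limits is unknown for the same reason. The main counts were 17 genes higher and 40 lower. Leaving out each strain in turn gave 8 to 23 higher and 12 to 50 lower, of which 5 to 9 and 10 to 27 were among the main calls. The low counts came without unipotent replicate 3 (8 and 19), multipotent replicate 2 (13 and 20) and multipotent replicate 3 (9 and 12), fits that also have fewer samples. At an adjusted p under 0.10 there were 69 and 134, and at an unadjusted p under 0.05 with a difference of at least 1 there were 196 and 280. Leaving out genes of low spread, which tests 11832 genes, gave 43 and 86. The cell cycle covariate, which takes up a residual degree of freedom, gave 10 and 14, of which 9 and 12 were among the main calls. The remaining alternatives stayed within 1.5 times of the main counts, at 16 to 25 higher and 38 to 56 lower.

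Of the 24 genes of largest difference past the threshold, 5 (OGN, SYNPO2, NRXN3, NRN1 and DLX1) passed without any single strain, 9 passed in at least 4 of those 6 fits, and SSTR1 and PDK3 passed in 0. None of the 24 reversed, and they kept between 1.24% (the other CARD16 probe set) and 114% of the difference. For the 57 genes past the threshold, 537 of 777 alternative values kept direction and call, 234 kept the direction and lost the call, and 6 reversed. The 79 other named genes kept both in 1029 of 1072 values, gained a call in 39 and reversed in 4. The reversals came from the genes' other probe sets with 1 symbol, and those with several symbols were not counted. They were at 0.17 for MCAM, 0.067 for KLHL3, 0.056 for RASIP1, 0.057 for E2F1, 0.045 for TEK and 0.023 for ACTG2. The first 3 genes reversed to the same values without probe sets ending in _s_at and _x_at, and TEK ranged from -1.51 to 0.60 without single strains. The cause was not tested.

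Camera passed 6 lists, against 0 with an estimated correlation, 3 in fry and 4 to 10 without single strains, the 10 being without multipotent replicate 2. The direction of 8 list means changed without single strains, with ranges of -0.27 to 0.44 for cell cycle genes, -0.11 to 0.14 for collagens and matrix proteins, -0.16 to 0.20 for endothelial markers, -0.010 to 0.037 for genes of inherited level differences, -0.14 to 0.040 for haematopoietic markers, -0.062 to 0.41 for inflammatory genes, -0.075 to 0.11 for matrix proteases and -0.16 to 0.058 for TGF-beta and BMP genes. Without probe sets ending in _s_at and _x_at the endothelial mean was -0.013 and that of inherited level differences -0.022. Among 325 list values, 281 kept direction and call. The log2 ratio of spread was 0.047 after quantile normalization and -0.14 to 0.62 without single strains, where the SD of 2 strains has a smaller median than that of 3 by construction, while the difference in similarity was 0.32 with Spearman correlation and 0.46 to 0.60 without single strains. The cause was not tested.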

Other observations

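The tests of RNA degradation and of the range of the cell cycle mean were chosen after the result was seen, as were the genes described first.

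Among the genes past the threshold that are not among their 24 largest differences, PTPN20 had the smallest p. This protein tyrosine phosphatase gene was lower in multipotent strains by a difference of -2.94 (SE 0.10, adjusted p = 0.0011). CD274, which encodes the immune checkpoint ligand PD-L1, differed by -2.68 (SE 0.21, adjusted p = 0.015), with -0.31 in its other probe set. CCND1, which encodes cyclin D1, differed by -1.05 (SE 0.12, adjusted p = 0.035), while the cell cycle list did not differ. When every probe set was tested in limma, its other probe set did not pass (-0.67, adjusted p = 0.49). HOXA11-AS, an antisense transcript of the HOXA cluster, differed by -0.92 (SE 0.09), and both of its probe sets passed. Of the 6 fits that left out 1 strain, PTPN20 passed in 6 and CD274 in 5, but CCND1 and HOXA11-AS in 0.

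Some of the largest differences did not pass, because strains of the same group were far apart. The WNT antagonist gene SFRP2 differed by 5.05 (SE 1.71, adjusted p = 0.33), at 4.41 ± 3.66 in multipotent and -0.64 ± 0.13 in unipotent strains (SD, n = 3 each), and by 3.36 without multipotent replicate 3. ASPN, which encodes asporin, a proteoglycan of the same family as osteoglycin and osteomodulin, differed by 4.72 (SE 1.25, adjusted p = 0.23). The chemokine receptor gene ACKR3 differed by 4.77 (adjusted p = 0.084; its other probe sets gave 0.25 and 2.22) and EPB41L3 by 4.34 (adjusted p = 0.088), and the ephrin gene EFNB2 by -4.79 (adjusted p = 0.088) and CCN6 by -4.70 (adjusted p = 0.079), although the other CCN6 probe set gave -0.023. In all 6 genes the groups did not overlap.

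The count of genes past the threshold was set against the other ways to split the 6 arrays 3 against 3. The real split was the 1 of 10 with as many genes, for the 17 higher and for the 40 lower, and the highest of the other splits had 1 in a direction. The count of shifted lists was 6 in the real split and as high as 8 in another, and 5 of the 10 splits had at least 6. With 10 splits no share under 0.05 can be reached. A list count of this size is therefore also found in splits that ignore the groups.

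Contractile genes were lower in multipotent strains by a mean of -1.40 (camera adjusted p = 0.33 with an estimated correlation), and 3 technical explanations were tested. RNA degradation would part the groups in the 5' minus 3' signal of the actin and GAPDH control probe sets, but the groups overlapped there (-0.03 ± 0.06 against -0.04 ± 0.16, SD, n = 3 each; difference 0.011). A different growth state, as far as cell cycle genes show it, would part the groups in the cell cycle mean, but all unipotent strains (-0.19 to 0.38) lay within the multipotent range (-0.52 to 0.91), so that this mean as a covariate had little to remove (difference -1.42, SE 0.25). Probe sets that match several transcripts would carry the shift, but without those ending in _s_at and _x_at it was -1.19 and the groups still did not overlap. These values argue against probe sets that match several transcripts as the whole cause. For RNA degradation and growth state they are weaker. They show only that the actin and GAPDH controls and the cell cycle mean did not part the groups, while the contractile list did. The hypothesis stays open that contractile genes may differ with differentiation potential, and culture density and donor were not tested on this list.

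If the groups came from different donors, genes of commonly inherited level differences could separate them more often than other genes. Of 24 such genes 3 had groups that did not overlap (12.5%), against a mean of 4.33 in random lists of matched spread (one-sided permutation p = 0.84 for more and 0.35 for fewer). Neither bound was reached, so different donors and differentiation potential cannot be told apart as sources of the genes that separate the strains. A further hypothesis was that genes next to each other in the genome are regulated together. Among the 200 genes of smallest p there were 3 neighbouring pairs with the same direction. They were DNM3 and its antisense transcript DNM3OS, KRTAP1-5 and KRTAP1-3, and HOXB3 and HOXB4. Random sets had a mean of 2.08 pairs (permutation p = 0.35), so the number of pairs was within chance. Only pairs with both genes among these 200 were counted. The count therefore neither shows nor excludes shared regulation of neighbouring genes.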
